A study of Homo sapiens with 3 samples.

How the data were processed

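Binding of estrogen receptor alpha (ERα, a nuclear receptor that activates genes when estrogen binds it) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7, an established ERα-positive line from a human breast adenocarcinoma. Per the labels' protocols, cells spent 3 days in medium without phenol red and with 5% charcoal-stripped serum, which removes most estrogen, and were transfected on day 2. In all, 3 kinds of library were made, with 1 library each. The first was an ERα immunoprecipitate from cells given a non-targeting control siRNA, the second an ERα immunoprecipitate from cells given siRNAs against ERα, and the third an immunoprecipitate with control rabbit IgG. Chromatin was fixed with 1% formaldehyde, and 10 ng of precipitated DNA from 240 µg of chromatin entered each library, per the labels' protocols. The IgG library carries no transfection label. There were no replicate libraries, so no effect of the siRNA was tested and no p-value here refers to a difference between conditions.

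The authors deposited 1 list of 4232 genomic intervals for the whole series. It has 3 columns, chromosome, start and end, and no score, height, fold or p-value and no value per library. The submitters' processing notes name the build hg19 (GRCh37). The aligner, the peak caller, its threshold, the control it used, and how the control siRNA, ERα siRNA and IgG libraries entered the calling are not given in the sources used here. Whether the list holds all ERα sites of the control cells or only those lost after ERα siRNA is therefore also not given. Sequencing depth is unknown. The starts were read as 0-based, as the format defines, and positions are printed 1-based in hg19. The order of the intervals in the list is also undocumented. It is used here only as a position from 1 to 4232.

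Site width was end minus start. Neighbouring sites were compared by the gap between their edges, and sites with gaps of at most 10 kb were chained into clusters. The share of sites within 10 kb of the next site was set against 1000 random placements of the same widths on the same chromosomes. This gave a one-sided permutation p whose smallest possible value is 0.000999. The plan had been to place sites in known sequence of the same build. No genome of that build was used here, so the span from the first to the last site of each chromosome took its place. Site counts per chromosome were compared with each chromosome's share of the summed span (2905 Mb) by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over 23 chromosomes. This density test was added after the data were seen, since the plan foresaw counts alone without a genome. It treats sites as independent, so the chromosomes were also compared by 100000 permutations of 5 Mb bins (two-sided). These keep neighbouring sites within a bin together but treat the bins as independent. Intervals for counts are exact 95% Poisson intervals and those for shares exact 95% Clopper-Pearson intervals. They cover counting error only.

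Sites wider than 1000 bp were called wide, and wide sites within 5 Mb of one another were joined into blocks if there were at least 5 of them. Segments were defined in the same way with a distance of 1 Mb. Both definitions were made after the widths had been seen. The clusters named in the text are the 5 with most sites, with ties going to the shorter cluster, a rule fixed before the data were examined. The densest windows were chosen without overlap, each starting at a site. Their intervals do not allow for this choice, and a density above the average of the chromosome largely follows from it.

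Other choices fixed before the data were examined were the 10 kb distance and its alternatives of 5 kb and 50 kb, the merging of overlapping sites, counting each cluster once, and leaving out chromosomes 17 and 20. Planned results that need gene positions or sequence of the list's build were not analysed here. These were the location of sites relative to genes, the content of 20 motifs, the nearness of 13 gene lists, and the density in amplicons bounded by named genes. The only gene table at hand was for another build (GRCh38), and coordinates were not converted, so no site is assigned to a gene. The part of the rule for named genes that gives genes therefore named none, including ESR1, the gene targeted by the siRNA.

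The tests were checked on simulated lists of 4232 sites. With even placement, the binomial test called any chromosome in 2 of 50 lists and the clustering test called 0 of 50. With chromosome 20 at 2 times and chromosome 18 at 0.5 times the even density, both were called in 50 of 50 lists by the binomial test and in 49 of 50 by the bin permutation. In lists with even chromosomes and 200 sites moved to within 8 kb of another, the bin permutation called any chromosome in 3 of 50. Dense stretches longer than a bin were not simulated. With 200 sites moved to within 8 kb of another, the clustering test called 50 of 50. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.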

Results

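The series asked where ERα contacts DNA in MCF-7 cells kept in medium with most estrogen removed, and included cells given siRNA against the receptor. The data analysed were the authors' list of 4232 binding sites in hg19. The series held a control siRNA library, an ERα siRNA library and an IgG library, with 1 library in each group. The list gave no value for any single library. The difference in occupancy between control and ERα siRNA cells was therefore not analysed here, and the sites are described as 1 set.

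The 4232 sites lay on the 22 autosomes and the X chromosome and covered 1994 kb. Their median width was 419 bp (95% bootstrap interval 415 to 423), with the middle 50% of sites between 320 and 504 bp. The narrowest site measured 61 bp and the widest 8744 bp. No sites overlapped or touched, and the smallest gap between neighbours was 3 bp.

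With all sites counted, chromosomes 20 and 17 had the highest densities of ERα sites. Chromosome 20 held 244 sites, or 3.96 per Mb of span (95% interval 3.47 to 4.48), 2.71 times the number an even spread would give. Chromosome 17 held 240 sites, or 3.01 per Mb (2.65 to 3.42), 2.07 times the even number. The sparsest were the X chromosome with 85 sites and 0.571 per Mb (0.456 to 0.706), chromosome 18 with 49 sites and 0.642 per Mb (0.475 to 0.849), and chromosome 4 with 147 sites and 0.774 per Mb (0.654 to 0.91). All chromosomes together had 1.46 sites per Mb. The list measures no copy number. Whether gains or losses of DNA copies in MCF-7 changed the number of sites detected per chromosome was not tested.

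By the exact binomial test, 8 chromosomes lay above an even spread and 6 below it after adjustment over 23 tests. The adjusted p was 6.47e-41 for chromosome 20, 1.08e-23 for chromosome 17, 3.91e-24 for X, 1.59e-10 for chromosome 18 and 1.22e-17 for chromosome 4. These 5 were also called when 5 Mb bins were permuted over chromosomes, with adjusted p of 0.00997, 0.0364, 0.00046, 0.0129 and 0.00391, in the same order. The remaining calls of the binomial test did not pass that permutation. They covered chromosomes 14, 15, 16, 19, 21 and 22, at 1.26 to 1.65 times the even number, and chromosomes 2, 5 and 13, at 0.612 to 0.874 times. Chromosome 1 had the most sites in absolute number, 343, but its density of 1.39 per Mb differed from the even spread by less than counting error (exact binomial test, adjusted p = 0.436).

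**Figure D1:**
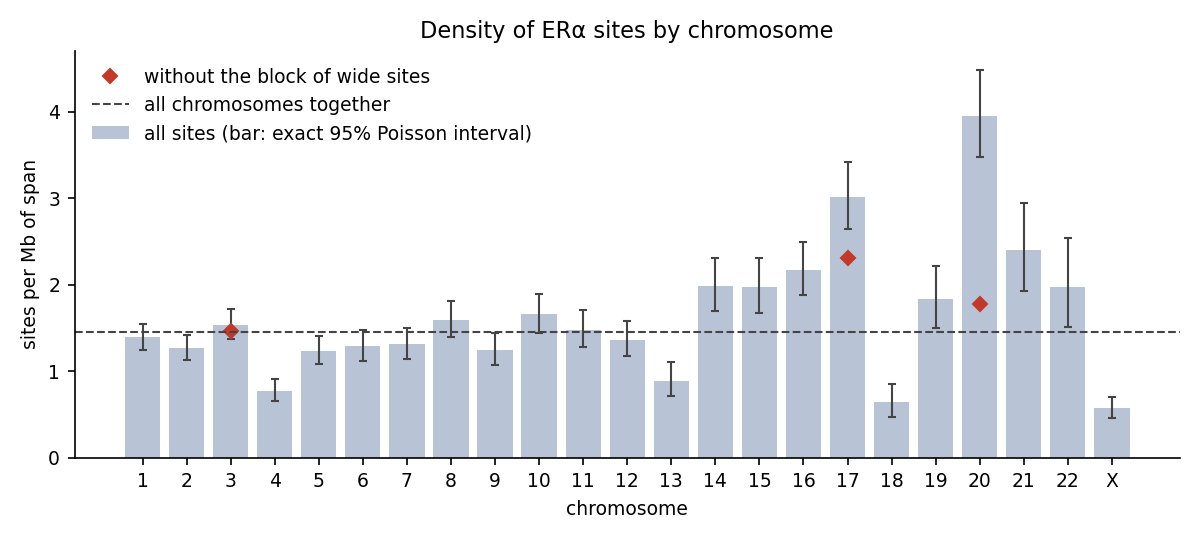
Sites per Mb of span (y axis, from first to last site) for each chromosome (x axis), with exact 95% Poisson intervals for counting error; the dashed line is the density over all chromosomes, 1.46 per Mb. Diamonds give chromosomes 3, 17 and 20 without their block of wide sites, where chromosome 20 fell from 3.96 to 1.78 per Mb and chromosome 17 from 3.01 to 2.32.

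Much of the density on chromosomes 17 and 20 came from a part of each. On chromosome 20, 152 of the 244 sites lay between positions 45882278 and 55853949, at 15.2 sites per Mb (12.9 to 17.9), against 1.78 per Mb (1.43 to 2.18) on the rest of the chromosome. On chromosome 17, 66 of the 240 sites lay between 55434739 and 59941899, at 14.6 per Mb (11.3 to 18.6), against 2.32 per Mb (1.99 to 2.69) elsewhere. A smaller stretch of chromosome 3, from 61989115 to 64504529, held 17 sites at 6.76 per Mb (3.94 to 10.8), against 1.47 per Mb (1.3 to 1.65) elsewhere. The ratios of density in the stretch to the rest were 8.57, 6.32 and 4.59 for chromosomes 20, 17 and 3. The adjusted p of the exact binomial test within each chromosome was 1.34e-58, 4.00e-27 and 5.62e-07, respectively. The limits of these blocks were set from the positions of wide sites in the same list, so these p-values are not independent of that choice. MCF-7 is known to carry extra copies on the long arms of chromosomes 17 and 20, which can give more reads without more binding. Whether extra copies raised the number of sites detected in these stretches was not tested. Without the blocks, the exact binomial test placed chromosome 20 at 1.29 times the even number (adjusted p = 0.035) and chromosome 17 at 1.67 times (adjusted p = 1.62e-09). The ranking then changed: chromosome 21 was the densest at 2.40 per Mb, followed by chromosome 17 at 2.32 and chromosome 16 at 2.17, and chromosome 20 at 1.78 also came after chromosomes 14, 15, 19 and 22.

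Wide sites were almost confined to these blocks. Of the 4232 sites, 130 (3.07%, 95% interval 2.57 to 3.64) were wider than 1000 bp, and 123 of them lay in the blocks on chromosomes 20 (81 sites), 17 (30 sites) and 3 (12 sites). The 57 sites wider than 2000 bp all lay there. The blocks held 5.55% of the sites but 18.4% of the summed width. Within the blocks, 53.3% of the chromosome 20 sites (45.0 to 61.4), 45.5% of the chromosome 17 sites (33.1 to 58.2) and 70.6% of the chromosome 3 sites (44.0 to 89.7) were wide. On the rest of these chromosomes, 0 of 92, 0 of 174 and 0 of 281 sites were wide, with upper limits of 3.93%, 2.1% and 1.3%. By construction of the blocks, wide sites on these chromosomes tend to fall inside them, and the intervals and upper limits of these shares do not allow for that. The widest site, of 8744 bp, spanned 52553247 to 52561990 on chromosome 20, and the next, of 8453 bp, spanned 59487195 to 59495647 on chromosome 17. The widest on chromosome 3 covered 7408 bp from 64142521 to 64149928. Outside the blocks the median width was 413 bp, the 95th percentile 628 bp and the widest site 1865 bp.

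**Figure D2:**
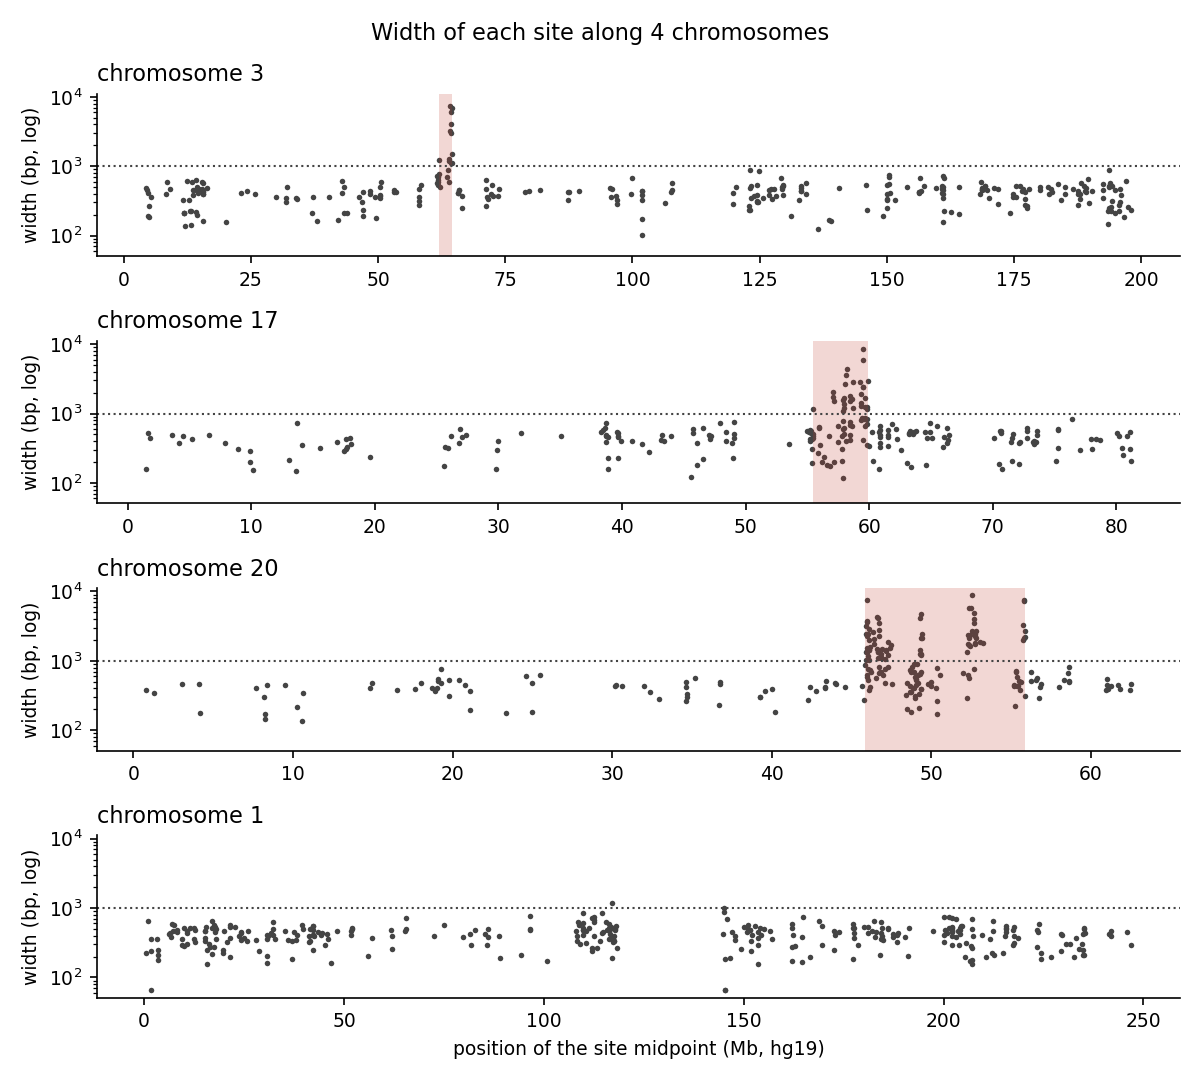
Width of each site in bp (y axis, log scale) against its midpoint in Mb of hg19 (x axis) on chromosomes 3, 17, 20 and, for comparison, 1; each point is a site, shading marks the blocks and the dotted line 1000 bp. The 12, 30 and 81 wide sites of chromosomes 3, 17 and 20 stand in the shaded blocks, and chromosome 1 has 1 wide site among 343.

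ERα sites also lay in small groups across the genome. In all, 612 sites (14.5%) lay within 10 kb of the next site, against a median of 1.75% in 1000 random placements on the same chromosomes (central 95% of placements 1.37 to 2.15%). This was 8.27 times the random share, with a permutation p of 0.000999, the smallest these placements can give. The excess was present at 5 kb (9.66% against 0.922%) and at 50 kb (30.7% against 8.15%). Without chromosomes 17 and 20 it was 13.3% against 1.52%, and each of these shares also had p = 0.000999 in the permutation test. Chaining at 10 kb left 3148 lone sites and 472 clusters of at least 2 sites, which held 25.6% of all sites.

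**Figure D3:**
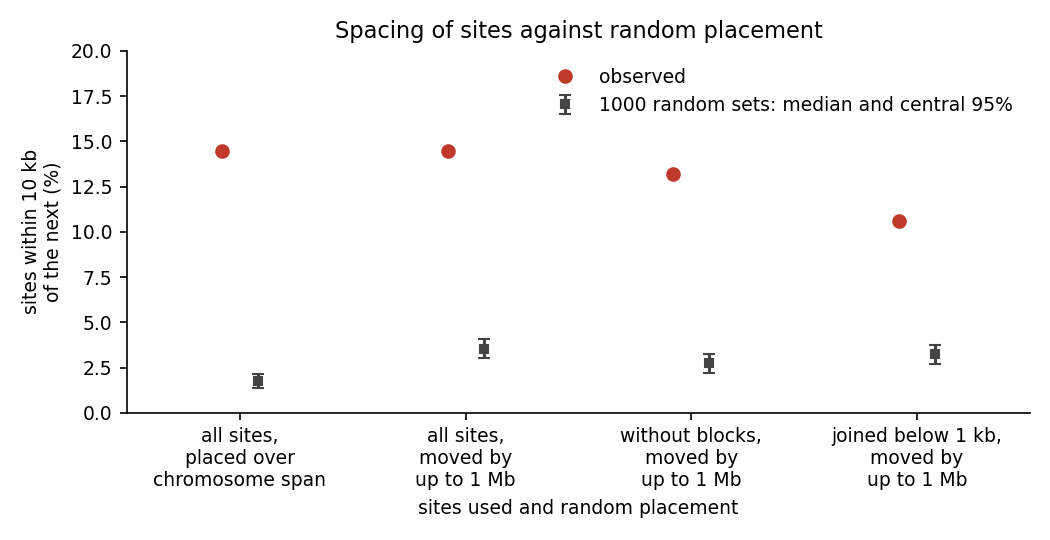
Percent of sites within 10 kb of the next site (y axis) as observed and in 1000 random sets (median with the central 95%), for 4 choices of sites and placement (x axis). The observed shares, from 10.6 to 14.5%, lie above every random range, of which the highest ends at 4.06%.

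The clusters with most sites were on chromosomes 17, 20, 19 and 22. A cluster of 8 sites on chromosome 17 ran over 28.8 kb, from 57906548 to 57935362, and another of 8 sites on chromosome 20 ran over 54.3 kb, from 45972923 to 46027216. Both lay in the blocks of wide sites. On chromosome 19, 6 sites lay within 7.01 kb, from 27731787 to 27738801, with a median width of 802 bp. This cluster bordered the longest stretch without a site on that chromosome, which measured 8.03 Mb. Whether the cluster lies in sequence that cannot be mapped uniquely was not tested, because no genome of the list's build was used. A cluster of 5 sites on chromosome 17 ran from 58422466 to 58434677, in the block, and 1 of 5 sites on chromosome 22 ran over 14.3 kb, from 29205069 to 29219346. Of the 29 clusters with at least 4 sites, 9 lay in the blocks and 20 elsewhere.

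At the scale of 1 Mb, 7 of the 10 densest windows touched the blocks. The densest, on chromosome 20 from 45882278, held 48 sites (95% interval 35.4 to 63.6), of which 35 were wide. The 3 others were on chromosome 8 from 101707353 with 17 sites (9.9 to 27.2), chromosome 16 from 84758126 with 16 sites (9.15 to 26.0) and chromosome 19 from 15590224 with 16 sites (9.15 to 26.0). None of these 3 windows held a wide site, and their median widths were 437, 454 and 314 bp.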

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

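Of 30 alternatives over 8 results, none reversed a value, and 24 kept the side of the threshold or, without a test, stayed within a limit. The limit was 1.5 times for a count, and the 95% interval for the median width (bootstrap) and for a share (binomial). Among the 24, chromosome 20 fell from 2.71 to 1.29 times the even density without the blocks (exact binomial test, adjusted p = 0.035), where no bin permutation was run. The number of sites stayed at 4232 when overlapping sites were merged, a void setting because none overlap. The share of close sites exceeded its random sets in each of 10 alternatives, 3 planned and 7 chosen after seeing the data. Of these, 8 used the distance of 10 kb and the others 5 kb and 50 kb. The median width moved from 419 bp to 487 bp in the first 2116 sites of the list and to 413 bp without the blocks. Chromosomes off an even density numbered 14 by the binomial test and 5 by permutation of 5 Mb bins, while 3 other settings gave 12 to 16. Of these calls, 2 above (17 and 20) and 3 below (4, 18 and X) were shared by all 5 settings. The share of wide sites on chromosomes 3, 17 and 20 was 94.6% above 1000 bp, 71.2% above 750 bp, 98.8% above 1500 bp and 100% above 2000 bp, and the 750 bp limit added a block on chromosome 8. Counting each cluster once left 180 sites on chromosome 20. A stricter score threshold and full chromosome lengths were not run, because the list has no score and no genome of its build was used. No paired analysis was possible because each group has 1 library and the list has no value per library. Depth is unknown, so its limits cannot be stated.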

Other observations

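Only the tests of the width of sites of at most 1000 bp, of sites moved by up to 1 Mb, of joined sites and of the correlation in the blocks were written down before their result, and the other tests and groupings of this part were chosen after the data were seen. Within the blocks, most wide sites fell in shorter segments. When wide sites were chained at 1 Mb, 6 segments with a summed length of 6.37 Mb held 121 of the 130 wide sites of the whole list. The segments also held 172 of the 235 block sites. They were drawn around wide sites, and whether wide sites were gathered more tightly than other block sites was not tested. On chromosome 20 the segments ran from 45882278 to 47482496 (43 of 60 sites wide), 49296254 to 49417121 (9 of 12), 52239708 to 53265850 (22 of 26) and 55731137 to 55853949 (7 of 7). On chromosome 17 a segment from 57045677 to 59941899 had 29 of 55 sites wide, and on chromosome 3 a segment from 63898973 to 64504529 had 11 of 12.

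Other regions were rich in sites but held few or no wide ones. Among windows of 10 Mb, chromosomes 16 (from 80057869) and 21 (from 37560363) held 58 sites each (95% interval 44.04 to 74.98), with no wide site in either. Chromosome 11 from 63326299 held 56 sites, also with none wide, and chromosome 8 from 94130730 held 55 with 1 wide. A window of chromosome 1 from 107963041 held 47 sites (34.5 to 62.5), at 4.7 per Mb against 1.39 for the whole chromosome, with 1 wide. It ended close to the longest stretch without a site on chromosome 1, of 26.5 Mb. The 7 wide sites outside the blocks were spread over chromosomes 1, 5, 8, 16, 18, 19 and 21. These sites were likewise not checked against sequence that cannot be mapped uniquely.

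The gathering of wide sites was weighed first. Of the wide sites, 93.1% lay within 1 Mb of another, against at most 34.6% in 1000 shuffles of the widths, which argues against chance. In 1000 shuffles among sites with equally many listed neighbours within 50 kb the share was at most 63.1%, so listed neighbours do not account for all of it, but binding already joined into a wide site is not counted among them. If the list runs from strong to weak, the wide block sites were not its strongest as a set. Their median position was 2136 (1828 to 2410) among 4232 sites. As many of the widest sites elsewhere, down to 681 bp against 1033 bp in the blocks, had a median position of 492 (426 to 566). That second set was chosen by width, and width falls with list position outside the blocks. Its early position was largely given by that choice and decides nothing about strength. Within the blocks, wide sites stood earlier than the others (median 2136 against 2650), so a part for strength stays open. Joined close binding, broad binding particular to these regions, and extra DNA copies stay open and cannot be told apart. MCF-7 is known to carry extra copies on the long arms of chromosomes 17 and 20. The list measures no copy number in any block, that on chromosome 3 included. Sites of at most 1000 bp had a median width 82.5 bp larger in the blocks (permutation p = 9.999e-05). This compared 112 sites with 547 on the rest of chromosomes 3, 17 and 20. Sites are not independent replicates, and the block sites of each chromosome come from a single stretch. The differences were 59, 88.5 and 283 bp on chromosomes 17, 20 and 3, the last with 5 block sites. Extra copies that widen every site there would give this direction, but whether the other explanations would give it as well was not tested. How much of the difference comes from drawing blocks around wide sites was not tested.

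The close spacing of sites was weighed second. Uneven density over megabases did not account for all of it, since 14.5% of sites lay within 10 kb of the next and at most 4.56% did in 1000 sets with each site moved by up to 1 Mb. Splitting of single binding events into listed sites less than 1 kb apart did not account for all of it either. After such sites were joined, 10.6% remained close, against a highest value of 4.15% in the moved sets. Without the blocks these shares were 9.68% and 3.23%. Pieces of 1 event lying further apart would not have been joined, so wider splitting was not tested. Of the 612 close gaps, 184 were under 1 kb and 428 were larger. Groups of separate receptor contacts within single regulatory regions may be the source, as a hypothesis that the list without gene positions or sequence leaves untested. Sequence that cannot be mapped uniquely, and so can hold no site, would also draw sites together and was not tested.

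The order of the list was weighed last. Across sites, which are not independent replicates, width fell with list position (Spearman rho -0.66, permutation p = 1e-05, the smallest possible), from a median of 555 bp in the first 10% of the list to 279 bp in the last. Outside the blocks rho was -0.72, and in the blocks it was -0.21, weaker than in each of 10000 random sets of 235 sites from elsewhere (weakest -0.58). This is consistent with width in the blocks following something other than what orders the list, although the blocks were themselves drawn around wide sites. The median position of the block sites, 2271, lay within that of random sets (1856 to 2374, permutation p = 0.252), so no overall shift in the list was shown; 19.1% of them (14.3 to 24.8) and 13.8% of the wide ones (8.26 to 21.2) stood in its last 10%, and 10.2% of them (6.65 to 14.8) in its first. What the order stands for is not stated in the sources used here.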
